A study of Homo sapiens with 25 samples.

How the data were processed

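DND-41 cells were grown at 5 levels of histidine, and strand-specific libraries were made from total RNA, per the labels' protocols. The deposited table holds signal values, normalized counts per gene, that the authors made with DESeq2 1.44.0 after quantification with kallisto 0.50.1 on GRCh38, with FastQC 0.11.9 also named, per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here. The table has 31919 genes, of which 9278 are named by an Ensembl ID, and 25 columns, each matched to a library by its label. Coordinates of named genes were looked up by symbol in GENCODE 29 on GRCh38, which may not be the annotation the authors used.

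Groups follow the titles. One no-histidine library, replicate 1, has a title with day 6 and a time label with day 9. It was kept at day 6, and the fit was repeated without it. The series text names other days than the sample labels, and days are given here as on the samples. Replicate numbers were used only as names in the main fit. They served as a block in an alternative fit and in a check of same-number pairs.

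Values were searched for whole reads. With the best single step per library, between 37.8% and 76.1% of values under 20 lay within 0.05 of a whole multiple, so reads were not recovered, the count tests planned as alternatives for that case were not run, and depth is known only as the total of normalized counts. Size-factor scaling removes differences in total RNA per cell, and transcript-based quantification shares reads among near-identical copies.

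Genes with a normalized count of at least 10 in at least 2 libraries were kept, which left 18799. Values were taken to log2 with a pseudocount of 1 and fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend, 1 mean per group over the 9 groups and 16 residual degrees of freedom. Contrasts compared each histidine level with 100% of the same day, none with 12.5%, day 9 with day 6 at 100%, a slope per halving of histidine on each day, and the day by dose differences. P-values were two-sided and Benjamini-Hochberg adjusted within a contrast, with a threshold of 0.05. Of 32 gene lists 30 had at least 5 tested genes and were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The myeloid and erythroid lists had too few. Of 129 list calls in the planned contrasts 13 held with an estimated correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

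Tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule took, for none against 100% on day 6 and for 12.5% against 100% on each day, the 6 largest rises and 6 largest falls past the threshold with a mean of at least 50 in the higher group, a gene symbol and no overlap between libraries, plus up to 4 members of each list that passed. It took 3 each way for the other comparisons of doses and for day, 2 each way for slopes and interactions, and HARS1, ASNS, DDIT3, TRIB3, CHAC1, SLC7A11, HMGCS1, MYC, HES1, CDKN1A and MKI67 whatever their values. Some genes that the rule takes are not reported here.

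The procedure was tested on simulated data. For none against 100% on day 6, with 17763 genes simulated, it recovered 35% of genes changed by 0.5 on the log2 scale, 77.5% of those changed by 1 and 90% of those changed by 2, with 3.52% of calls false. For 12.5% on day 9 it recovered 25%, 70% and 90% (4.58% false). For the day by dose difference at 12.5% it recovered only 10%, 55% and 85% (3.81% false), so differences of that size can be missed. Simulated genes varied independently, with 200 changed in a comparison and no shared differences between libraries beyond size. The real libraries hold more changes and may share such differences, so these rates may be too favourable. The alternatives were other pseudocounts and filters, upper-quartile rescaling, quantile normalization, no mean trend, library weights, a replicate block, a fit on the compared groups, rank and estimated-correlation list tests and leaving out each library. After the data were examined, covariates for keratin and 5.8S rRNA and a fit without libraries high in keratin were added.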

Results

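RNA sequencing was carried out on DND-41, a human T-cell acute lymphoblastic leukaemia line, grown in media with graded amounts of histidine, an essential amino acid. The 25 libraries fell into 9 groups. On day 6 there were 3 libraries each at 100%, 50%, 12.5% and no histidine and 2 at 25%, and on day 9 there were 3 each at 100%, 25% and 12.5% and 2 at 50%. Each library held between 14425 and 16263 genes with a normalized count of at least 10, and its normalized counts added up to between 13.6 M and 16.1 M. Original read totals were not recoverable from these normalized counts. The 10 most abundant genes took between 3.96% and 5.77% of each total. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Changes below are on the log2(normalized count + 1) scale with limma's moderated test, Benjamini-Hochberg adjusted over 18799 genes, and group values are mean ± SD. This scale understates changes of low genes. The libraries of one group correlated at between 0.964 and 0.972 in log2 counts, and the highest correlation between groups was 0.973.

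The first question was how far expression moved at each histidine level. At 50% histidine no gene passed the threshold on day 6 in the limma test, where 695 genes had an unadjusted p under 0.05. On day 9 a single gene, SENP3-EIF4A1, passed at 50%, with 10.5 ± 8.40 normalized counts (n = 2) against 55.6 ± 10.4 (n = 3) in full medium (log2 change -2.51, adjusted p = 0.0465), and 906 genes had an unadjusted p under 0.05. SENP3-EIF4A1 is a readthrough of neighbouring genes that share its reads, so its level is uncertain, and leaving out any one of the day 9 libraries at 100% or replicate 1 at 50% ended its call. So did a pseudocount of 8, no mean trend, quantile normalization, the replicate block, library weights, the keratin covariate, leaving out the keratin-high libraries described below and a fit on the compared groups. With a pseudocount of 8 or no mean trend the only gene called was another one, which rose. Leaving out either 50% library of day 9 left 1 in that group, which is then assumed to vary like the other groups. With estimated library weights 292 genes passed on day 6. With the preset correlation 7 lists passed at 50% on day 6 and 5 on day 9, though at most 1 gene passed, and none did with an estimated correlation (lowest adjusted p = 0.442 for histones and 0.782 for G2/M and mitosis). At 25% histidine 2577 genes changed on day 6 and 3415 on day 9. At 12.5% the numbers were 5072 and 3916, and without histidine 5611 genes changed on day 6. The 25% group of day 6 had 2 libraries and the others in these counts 3. Its median SE was 0.244 against 0.218, which lowers its count relative to the others.

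**Figure D1:**
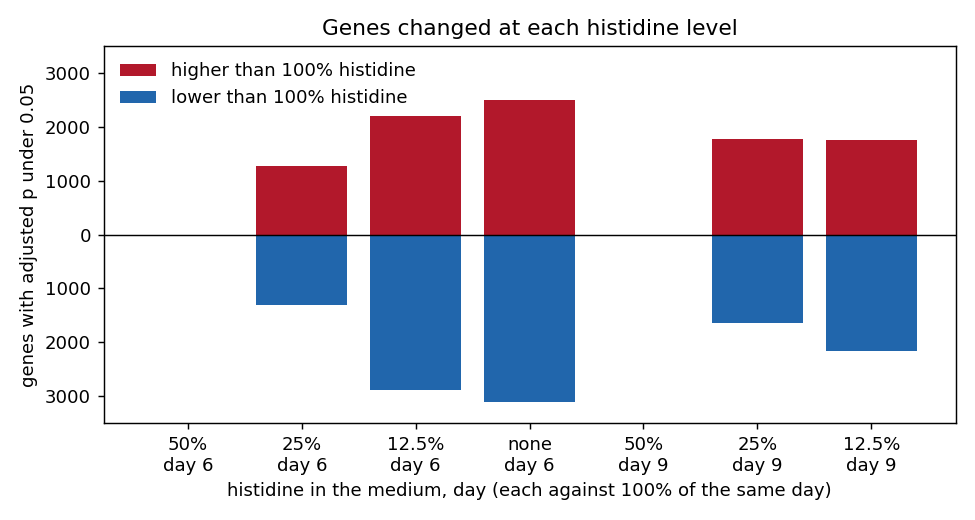
Number of genes with an adjusted p under 0.05 (y axis) against 100% histidine of the same day for each histidine level and day (x axis), with genes that were higher drawn upwards and genes that were lower drawn downwards. Both 50% groups are at or near 0 (0 genes on day 6 and 1 on day 9), and the no-histidine group has 2503 genes higher and 3108 lower.

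At 12.5% histidine on day 6, genes of lipid synthesis and of DNA replication were lower than in full medium. Of 23 tested genes of cholesterol synthesis, 20 fell and none rose (20 adjusted over the list alone), with a median log2 change of -1.18. DHCR7, which carries out the last step to cholesterol, fell from 1896 ± 98.4 to 469 ± 111 normalized counts (log2 change -2.04 ± 0.15 SE, adjusted p = 3.34e-09), n = 3 in each group. HMGCS1, LSS, MVD and INSIG1 fell by between 1.29 and 1.48 on the log2 scale. The stearoyl-CoA desaturase SCD (chromosome 10, 100347124 to 100364834 of GRCh38) fell from 24568 ± 2229.6 to 6502 ± 191 normalized counts (log2 change -1.91 ± 0.09 SE, adjusted p = 1.49e-12), and the fatty acid desaturase FADS2 had a log2 change of -1.96, with FADS1 also lower. Of 12 genes of fatty acid synthesis 9 fell (10 adjusted over the list alone). The cholesterol list stood apart from other genes with an estimated correlation (adjusted p = 0.0397), while the fatty acid list did so with the preset correlation (adjusted p = 2.04e-09) and not with the estimated one (adjusted p = 0.0687 with an estimated correlation).

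Of 30 genes of G1/S and DNA replication, 25 fell at 12.5% on day 6 (25 adjusted over the list alone), with a median log2 change of -0.56 and an adjusted p = 0.103 with an estimated correlation. The replicative helicase subunit MCM2 (chromosome 3, 127598223 to 127622436) went from 9385 ± 493 to 2970.0 ± 199 normalized counts (log2 change -1.66 ± 0.10 SE, adjusted p = 7.54e-11). FEN1 and the chromatin assembly factor CHAF1B had log2 changes of -1.18 and -1.15. Thymidylate synthase TYMS, with 3971 ± 995 against 10781 ± 349 normalized counts, was among 7 of 16 genes of serine and one-carbon metabolism that fell (8 adjusted over the list alone, adjusted p = 0.456 with an estimated correlation). Mitotic genes went both ways. Of 30, 5 rose and 9 fell (5 and 16 adjusted over the list alone, adjusted p = 0.642 with an estimated correlation). NUSAP1 and ANLN rose by 0.59 and 0.55 on the log2 scale, and the mitotic kinase AURKB fell by 1.54.

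Ranked by size among genes with a mean of at least 50 in the higher group and no overlap between libraries, the largest rises at 12.5% on day 6 were in CCND2, ANKRD20A2P, TTC28-AS1, DOK3, CDCP1 and MMP9. Every ranking by size here keeps these limits. The signalling adaptor DOK3 rose from 17.3 ± 10.8 to 116 ± 19.1 normalized counts (log2 change 2.93 ± 0.38 SE, adjusted p = 5.15e-06), the membrane protein CDCP1 from 14.5 ± 6.55 to 109.9 ± 8.79 normalized counts (log2 change 2.92 ± 0.31 SE, adjusted p = 4.16e-07) and the matrix metalloproteinase MMP9 from 8.15 ± 4.12 to 54.2 ± 10 normalized counts (log2 change 2.70 ± 0.46 SE, adjusted p = 0.000114). Cyclin D2 (CCND2, chromosome 12, 4273772 to 4305350) was at 104 ± 50.2 against 6.64 ± 6.97 normalized counts (log2 change 4.38, adjusted p = 0.00453). It did not pass with the 5.8S rRNA level as a covariate (3.81 ± 1.501 SE, adjusted p = 0.0774, from 4.38 ± 1.10 SE). That level was lower in each 12.5% library than in each 100% library of day 6, so this covariate can also remove an effect of histidine. ANKRD20A2P, a pseudogene, and TTC28-AS1, an antisense RNA, had adjusted p = 0.0354 and 0.0255. Leaving out 100% replicate 1 or 12.5% replicate 1 or 2 ended either call, and so did 100% replicate 3 or 12.5% replicate 3 for ANKRD20A2P and 100% replicate 2 for TTC28-AS1. The largest falls were in 7SK, SCARNA2, SEPTIN5, H4C3, NOMO3 and the aminoacylase ACY1. 7SK and SCARNA2, which lack poly(A) tails, were listed at 0 in the 3 libraries at 12.5%. Among other libraries, 7SK was also at 0 in 100% replicates 1 and 3 of day 9 and in 50% replicate 1 and 25% replicate 3 of day 6. Its zeros are thus not particular to low histidine. The log2 changes of 7SK and SCARNA2 at 12.5% were -7.06 ± 2.14 SE and -6.30 ± 1.83 SE. With the 5.8S rRNA level as a covariate these were -3.81 ± 2.75 SE and -5.13 ± 2.48 SE and neither passed (adjusted p = 0.356 and 0.153). Without the keratin-high libraries described below they were larger, at -8.17 ± 2.86 SE and -7.05 ± 2.33 SE, yet did not pass (adjusted p = 0.0717 and 0.0569) against the 1 remaining control. The call of 7SK also ended without 100% replicate 3. SEPTIN5 fell from 102 ± 28.6 to 10.2 ± 14.7 normalized counts (log2 change -4.32 ± 0.71 SE, adjusted p = 8.26e-05) and ACY1 from 128 ± 27.1 to 14.5 ± 10.4 normalized counts (log2 change -3.28 ± 0.37 SE, adjusted p = 1.01e-06). NOMO3 (log2 change -3.56 ± 0.70 SE, and -1.85 ± 0.91 SE with adjusted p = 0.203 against the 1 control without high keratin) and H4C3 have near-identical copies in the genome, so their levels are uncertain.

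Further lists passed with the preset correlation at 12.5% on day 6, and none of them held with an estimated one. Of 20 cytosolic tRNA synthetases 8 fell and 2 rose (8 and 2 adjusted over the list alone, adjusted p = 0.642 with an estimated correlation), with QARS1 at 1570.4 ± 214 against 3760.2 ± 131 normalized counts. Of 34 nuclear genes of oxidative phosphorylation 18 fell (19 adjusted over the list alone, adjusted p = 0.642 with an estimated correlation), led by CYC1 with a log2 change of -1.51. Of 39 ribosomal protein genes 15 fell (17 adjusted over the list alone, adjusted p = 0.642 with an estimated correlation). Of 21 genes of the unfolded protein response 13 fell (13 adjusted over the list alone, adjusted p = 0.428 with an estimated correlation). Of 29 genes of glycolysis and hypoxia 16 fell and 1, KDM3A (chosen after its values were seen), rose (16 and 2 adjusted over the list alone, adjusted p = 0.521 with an estimated correlation). Of 18 genes of the NRF2 and glutathione list 7 fell and 2 rose (8 and 2 adjusted over the list alone, adjusted p = 0.642 with an estimated correlation). Of 16 heat shock genes 8 rose and 2 fell (9 and 3 adjusted over the list alone, adjusted p = 0.642 with an estimated correlation), among them HSPH1 (log2 change 0.97, adjusted p = 2.21e-05) and HSP90AA1 (log2 change 0.83, adjusted p = 7.34e-05). Of 13 mitochondrially encoded genes 2 fell (2 adjusted over the list alone, adjusted p = 0.7 with an estimated correlation), and the sign of this list's median turned from -0.29 to 0.05 under quantile normalization.

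Of 29 replication-dependent histone genes 12 fell and 2 rose at 12.5% on day 6 (15 and 2 adjusted over the list alone, adjusted p = 0.642 with an estimated correlation). H4C1 fell from 159 ± 86.2 to 19 ± 7.35 normalized counts (log2 change -2.93 ± 0.41 SE, adjusted p = 1.19e-05), while H2AC6 rose from 106 ± 64.4 to 438 ± 31.9 normalized counts (log2 change 2.19 ± 0.26 SE, adjusted p = 2.09e-06). The 13 other tested RNAs without poly(A) tails moved with the histones, with a median log2 change of -1.59 against -1.22 for the histones. With the 5.8S rRNA level as a covariate the histone median turned to 0.10, while H4C1 and H2AC6 still passed in the same directions. 5.8S rRNA itself was at 74.8 to 88.2 normalized counts at 12.5% and 153 to 1181 at 100% on day 6. This covariate can therefore also remove an effect of histidine, and the fit cannot tell these apart. At 50% on day 6, where no gene passed, 5.8S rRNA was at 145 to 157 normalized counts and the histone median was -1.01. In all, 2196 genes rose and 2876 fell at 12.5% on day 6, so 43.3% of calls were rises. After rescaling to the upper quartile 54.5% were rises, and that scaling moved the median of all genes to 0.12 from 0.04. Leaving out the libraries with KRT8, KRT18 and KRT19 adding up to more than 100, among them 2 of the 3 controls, left 2464 genes.

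The same levels were compared on day 9 between other libraries, though the libraries of day 6 entered the shared estimate of the spread. Cholesterol synthesis genes were again lower, with 21 of 23 down and none up (21 adjusted over the list alone, median log2 change -1.19, adjusted p = 0.0136 with an estimated correlation). Sterol demethylase CYP51A1 fell from 427 ± 39.6 to 69.3 ± 9.72 normalized counts (log2 change -2.61 ± 0.22 SE, adjusted p = 2.14e-08), n = 3 in each group. HMGCS1, LSS and INSIG1 had log2 changes of -1.51, -1.38 and -1.48. Of 12 fatty acid synthesis genes 9 fell (10 adjusted over the list alone, adjusted p = 0.0167 with an estimated correlation), among them SCD, from 21288 ± 693 to 5802 ± 631 normalized counts (log2 change -1.88 ± 0.09 SE, adjusted p = 2.19e-12), FADS2 (-1.92) and FASN (-1.03). Of 30 genes of G1/S and DNA replication 19 fell (20 adjusted over the list alone, adjusted p = 0.21 with an estimated correlation), led by MCM2 at 4502 ± 280.4 against 11468 ± 859.7 normalized counts.

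The largest rises on day 9 at 12.5% were in CNTN4, CDRT4, SNHG12, GDAP1L1, FUT1 and MMP9. The snoRNA host gene SNHG12 rose from 127 ± 60.5 to 965 ± 116 normalized counts (log2 change 3.03 ± 0.30 SE, adjusted p = 1.73e-07), the fucosyltransferase FUT1 from 11.4 ± 3.5 to 90.8 ± 9.21 normalized counts (log2 change 2.92 ± 0.36 SE, adjusted p = 3.39e-06) and MMP9 from 13.9 ± 7.24 to 96.9 ± 17.6 normalized counts (log2 change 2.81 ± 0.46 SE, adjusted p = 9.67e-05). The adhesion molecule gene CNTN4 was at 55.1 ± 25.4 against 0.851 ± 0.863 normalized counts, and the call of CDRT4 (adjusted p = 0.014) ended without 12.5% replicate 3 or 100% replicate 3. Among the largest falls were those of GPC3, CYP51A1, CKAP4 and PACSIN3. CKAP4 fell from 134 ± 14 to 24 ± 6.09 normalized counts (log2 change -2.45 ± 0.30 SE, adjusted p = 2.78e-06) and PACSIN3 from 202 ± 19.3 to 37.5 ± 4.26 normalized counts (log2 change -2.40 ± 0.24 SE, adjusted p = 2.31e-07). The glypican gene GPC3 had a log2 change of -2.66.

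Other lists passed on day 9 at 12.5% with the preset correlation and not with an estimated one. Of 20 tRNA synthetases 7 fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.694 with an estimated correlation), with QARS1 at a log2 change of -1.30. Of 16 genes of serine and one-carbon metabolism 6 fell (6 adjusted over the list alone, adjusted p = 0.488 with an estimated correlation). Of 34 oxidative phosphorylation genes 6 fell (6 adjusted over the list alone, adjusted p = 0.694 with an estimated correlation), and of 13 mitochondrially encoded genes 3 rose (3 adjusted over the list alone, adjusted p = 0.694 with an estimated correlation). Of 29 glycolysis and hypoxia genes 10 fell and 1 rose (14 and 1 adjusted over the list alone, adjusted p = 0.472 with an estimated correlation), and of 21 genes of the unfolded protein response 9 fell (12 adjusted over the list alone, adjusted p = 0.488 with an estimated correlation). Of 30 MYC targets in ribosome biogenesis 9 fell and 2 rose (10 and 2 adjusted over the list alone, adjusted p = 0.694 with an estimated correlation). Of 16 heat shock genes 8 rose and 2 fell (9 and 3 adjusted over the list alone, adjusted p = 0.694 with an estimated correlation), among them HSPA1B with a log2 change of 1.08. Of 7 tested B-cell markers 4 fell (4 adjusted over the list alone, adjusted p = 0.182 with an estimated correlation). CD79A, at 16295 ± 1822 normalized counts in full medium, is abundant in DND-41 itself and had a log2 change of -0.66. EBF1 (adjusted p = 0.037) lost its call without 100% replicate 1 or 3 or 12.5% replicate 1 or 3.

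Of the 3916 genes changed at 12.5% on day 9, 1758 rose and 2158 fell, against 2163 and 1940 after upper-quartile rescaling. Between the days, 1056 genes rose at 12.5% on both, where independent lists would share 205, and 1633 fell on both, where independent lists would share 330.1. Only 8 genes were called in opposite directions. Across the 18799 genes, which are not independent replicates, log2 changes of the 2 days had a Pearson r of 0.439. At 25% histidine 974 genes rose on both days, against 120.1 for independent lists, 918 fell on both, against 113.9, and 2 were called in opposite directions.

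Without histidine on day 6, cell cycle genes of every phase tested were lower. Of 30 genes of G2/M and mitosis 29 fell (29 adjusted over the list alone, median log2 change -1.24), and of 30 genes of G1/S and DNA replication 29 fell (29 adjusted over the list alone, median -1.17). Both lists held with an estimated correlation (adjusted p = 0.0104 each). Topoisomerase TOP2A (chromosome 17, 40388516 to 40417950) fell from 18901 ± 1355 to 6342 ± 608 normalized counts (log2 change -1.58 ± 0.08 SE, adjusted p = 1.53e-12), n = 3 in each group, and the mitotic kinase AURKB from 3738 ± 50.3 to 698 ± 118 normalized counts (log2 change -2.43 ± 0.13 SE, adjusted p = 2.39e-12). The proliferation marker MKI67 had a log2 change of -1.32, the mitotic transcription factor FOXM1 -1.24, E2F2 -1.73, MCM10 -1.80 and MCM2 -1.85. The cell cycle inhibitor gene CDKN1A fell from 614 ± 38.4 to 193 ± 14.5 normalized counts (log2 change -1.66 ± 0.13 SE, adjusted p = 1.22e-09). TYMS (-2.17) and MTHFD1 were among 7 of 16 genes of serine and one-carbon metabolism that fell, with 1 that rose (7 and 1 adjusted over the list alone, adjusted p = 0.439 with an estimated correlation).

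Lipid synthesis genes were also lower without histidine. Of 23 cholesterol synthesis genes 18 fell (19 adjusted over the list alone) and of 12 fatty acid synthesis genes 11 fell (11 adjusted over the list alone), and both lists held with an estimated correlation (adjusted p = 0.0348 each). SCD went from 24568 ± 2229.6 to 5417 ± 349 normalized counts (log2 change -2.18 ± 0.09 SE, adjusted p = 2.16e-14). HMGCS1 (chromosome 5, 43289395 to 43313512), which makes HMG-CoA for cholesterol synthesis, went from 2986 ± 435 to 1107 ± 17.8 normalized counts (log2 change -1.42 ± 0.11 SE, adjusted p = 4.83e-10). FADS2, ELOVL6 and FDFT1 had log2 changes of -2.21, -1.13 and -1.31.

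The largest rises without histidine were in SLC26A11, CCND2, H3-7, CNTN4, H2AC6 and ARRDC3. ARRDC3, which encodes an arrestin-domain protein (chromosome 5, 91368724 to 91383359), rose from 332 ± 33.6 to 3846 ± 424 normalized counts (log2 change 3.53 ± 0.12 SE, adjusted p = 2.24e-15), the smallest p of this comparison. SLC26A11 rose from 2.34 ± 1.42 to 63.9 ± 11.6 normalized counts (log2 change 4.37 ± 0.66 SE, adjusted p = 1.49e-05) and H2AC6 from 106 ± 64.4 to 1194 ± 214 normalized counts (log2 change 3.63 ± 0.26 SE, adjusted p = 2.64e-10). CCND2 was at 99.1 ± 70.9 against 6.64 ± 6.97 normalized counts, and its call (adjusted p = 0.0084) ended without replicate 3 at 100%. Among the largest falls were those of SCARNA2, KRT18, GPC3, ADAM11 and H4C3. GPC3 fell from 119 ± 21.2 to 7.12 ± 7.17 normalized counts (log2 change -4.58 ± 0.62 SE, adjusted p = 3.62e-06) and ADAM11 from 73.3 ± 12.2 to 7.2 ± 11 normalized counts (log2 change -4.26 ± 0.91 SE, adjusted p = 0.000885). SCARNA2 was listed at 0 in the 3 no-histidine libraries, and did not pass with the 5.8S rRNA level as a covariate (log2 change -5.58 ± 2.12 SE, adjusted p = 0.0571, from -6.30 ± 1.83 SE). KRT18 (adjusted p = 0.0402, lost without 100% replicate 1 or 2 or any one no-histidine library) was high in 2 of the 3 control libraries, at 90.2 and 364.6 normalized counts against 2.74 in the third, and with PDGFRB it made 2 of 7 tested epithelial and fibroblast markers that fell (2 adjusted over the list alone, adjusted p = 0.411 with an estimated correlation). PDGFRB, at 1113 ± 82.4 normalized counts in full medium, is expressed in DND-41.

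Of 16 tested NOTCH1 targets 8 fell without histidine and none rose (8 adjusted over the list alone, adjusted p = 0.176 with an estimated correlation). CR2 fell from 333 ± 23.8 to 73.4 ± 11.5 normalized counts (log2 change -2.18 ± 0.15 SE, adjusted p = 1.72e-10) and DTX1, a regulator of NOTCH signalling, from 19014 ± 459.8 to 11734 ± 1255 normalized counts (log2 change -0.70 ± 0.11 SE, adjusted p = 1.78e-05), while RHOU and APCDD1 were under 100 normalized counts and HES1 had a log2 change of 0.04 (adjusted p = 0.788). Of 16 heat shock genes 10 rose and 1 fell (10 and 1 adjusted over the list alone, adjusted p = 0.392 with an estimated correlation), with the chaperone genes HSPA8, HSPH1 and HSP90AB1 at log2 changes of 1.22, 1.28 and 1.06. Of 27 lysosome and autophagy genes 12 rose and 2 fell (13 and 4 adjusted over the list alone, adjusted p = 0.439 with an estimated correlation), among them FNIP1, CTSD, ULK1 and RRAGC at 1.27, 0.91, 0.80 and 0.78. Of 30 MYC targets in ribosome biogenesis 13 rose and 2 fell (14 and 2 adjusted over the list alone, adjusted p = 0.719 with an estimated correlation). Of 39 ribosomal protein genes 7 rose (3 adjusted over the list alone, adjusted p = 0.929 with an estimated correlation), and the calls of RPS6, RPS3A, RPL6 and RPS12 ended without the keratin-high libraries. Their log2 changes were 0.78, 0.66, 0.45 and 0.55 (SE 0.17, 0.19, 0.13 and 0.18) with all libraries and 0.66, 0.59, 0.43 and 0.50 (SE 0.26, 0.29, 0.19 and 0.27) against the 1 remaining control. The calls of RPS3A, RPL6 and RPS12 also ended with the 5.8S rRNA level as a covariate or without no-histidine replicate 3, and that of RPS12 also without no-histidine replicate 2 or 100% replicate 1 or 2. In all 2503 genes rose and 3108 fell, against 3158 and 2786 after upper-quartile rescaling, and 3239 were called without those libraries.

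**Figure D2:**
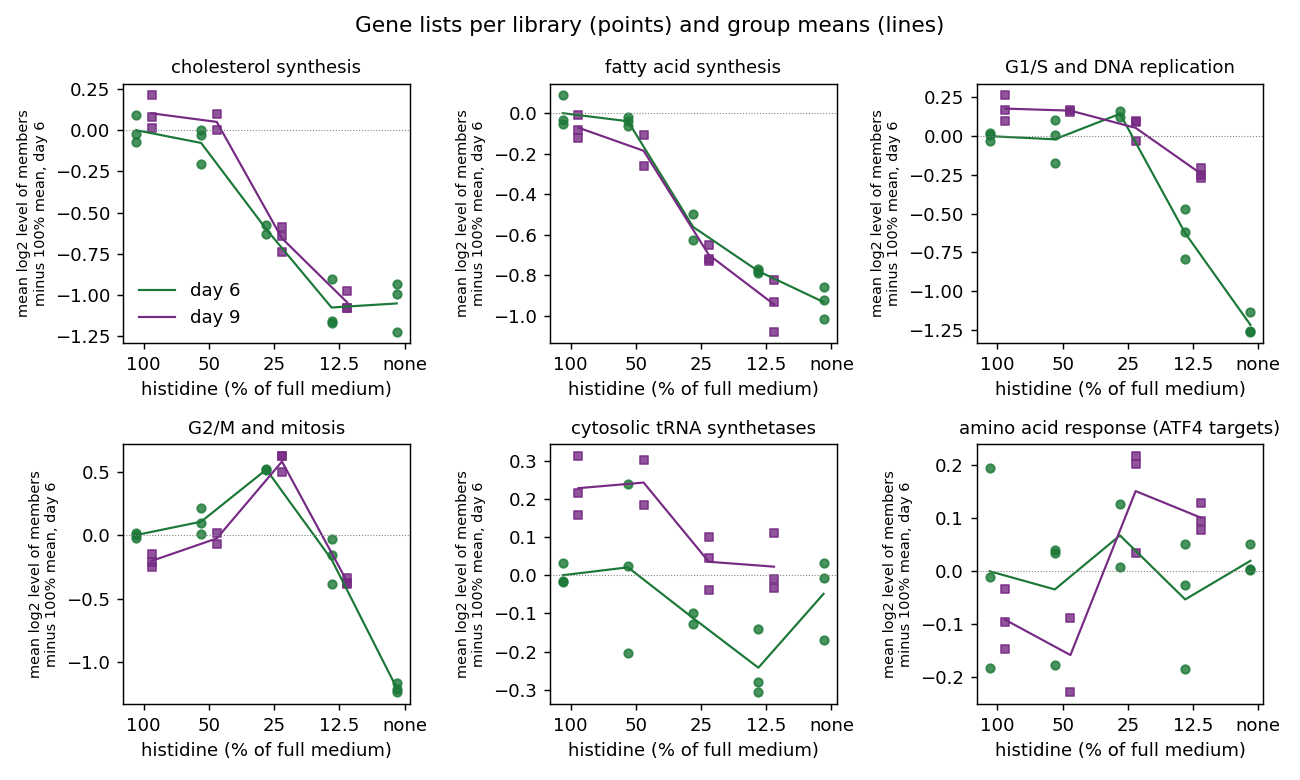
Mean log2 level of the members of 6 gene lists in each library (points) and group means (lines), minus the mean of the 100% libraries of day 6 (y axis, log2 units), against histidine in the medium (x axis, % of full medium) on day 6 (green) and day 9 (purple). Cholesterol and fatty acid genes are lower from 25% histidine on, and genes of G2/M and mitosis are higher at 25% (19 of 30 called up on day 6 and 27 on day 9) and lower without histidine (29 of 30 called down).

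No histidine was also compared with 12.5% directly on day 6, where 1316 genes rose and 1553 fell. Of 30 G2/M and mitosis genes 28 were lower without histidine (28 adjusted over the list alone, median log2 change -1.07, adjusted p = 0.0019 with an estimated correlation), among them MKI67, from 29788 ± 2354 to 9096 ± 1867 normalized counts (log2 change -1.73 ± 0.15 SE, adjusted p = 1.09e-08). Of 30 genes of G1/S and DNA replication 22 were lower (23 adjusted over the list alone, adjusted p = 0.06 with an estimated correlation). Of 39 ribosomal protein genes 27 were higher (38 adjusted over the list alone, adjusted p = 0.402 with an estimated correlation), and so were 14 of 30 MYC targets in ribosome biogenesis (15 adjusted over the list alone, adjusted p = 0.337 with an estimated correlation) and 11 of 21 genes of the unfolded protein response, of which 1 was lower (12 and 1 adjusted over the list alone, adjusted p = 0.315 with an estimated correlation). Across 12667 genes, which are not independent replicates, log2 change had a Spearman rho of -0.24 with coding length and 0.187 with the GC content of the coding sequence here. At 12.5% against 100% these were 0.18 and -0.131. The changes of the ribosomal protein genes were not separated from these trends. A further 11 lists passed with the preset correlation and not with an estimated one (adjusted p from 0.19 for NOTCH1 targets, of which 7 of 16 were lower and 1 higher, to 0.663 for oxidative phosphorylation, each with an estimated correlation). DDIT3 and TRIB3 were higher by 0.82 and 0.55 on the log2 scale, and HMGCS1 did not pass (log2 change -0.13, adjusted p = 0.491). By the rule of largest change NOMO3, ACY1 and PRMT7 rose and CASP8AP2, BLTP1 and ST3GAL6 fell. ACY1 rose from 14.5 ± 10.4 to 73.1 ± 11.6 normalized counts (log2 change 2.49 ± 0.37 SE, adjusted p = 5.26e-05), while the call of PRMT7 (adjusted p = 0.0232) ended without no-histidine replicate 2 or 3 or 12.5% replicate 2, that of BLTP1 (0.0307) without no-histidine replicate 3 or 12.5% replicate 1 or 2, and that of NOMO3 (0.00747) without no-histidine replicate 3 or 12.5% replicate 2. CASP8AP2 and ST3GAL6 lost their calls when only the compared groups were fitted. The total of 2869 genes became 1750 without no-histidine replicate 3, 1909 without replicate 2 and 1846 without 12.5% replicate 2, and was 4967 with estimated library weights and 1184 when only the compared groups were fitted.

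At 25% histidine mitotic genes were higher and lipid synthesis genes lower than in full medium on both days. Of 30 G2/M and mitosis genes 19 rose and 1 fell on day 6 (23 and 1 adjusted over the list alone, adjusted p = 0.0942 with an estimated correlation). On day 9, 27 rose and 1 fell (28 and 1 adjusted over the list alone, adjusted p = 0.0173 with an estimated correlation). Among members chosen after their values were seen, the mitotic kinase PLK1 had log2 changes of 0.98 and 1.59 on days 6 and 9, and the kinesin KIF20A 0.51 and 1.21. Of 23 cholesterol synthesis genes 13 fell on day 6 (15 adjusted over the list alone, adjusted p = 0.0942 with an estimated correlation) and 17 on day 9 (19 fell and 1 rose adjusted over the list alone, adjusted p = 0.0467 with an estimated correlation). Of 12 fatty acid synthesis genes 6 and 8 fell (9 and 9 adjusted over the list alone, adjusted p = 0.0942 and 0.0517 with an estimated correlation). Of 30 MYC targets in ribosome biogenesis 15 fell and 1 rose on day 6 (19 and 2 adjusted over the list alone, adjusted p = 0.408 with an estimated correlation) and 12 fell and 1 rose on day 9 (16 and 1 adjusted over the list alone, adjusted p = 0.51 with an estimated correlation). Of 15 NF-kB and inflammatory genes 6 rose on each day (6 rose and 1 fell on day 6 and 7 rose on day 9, adjusted over the list alone), with adjusted p = 0.211 and 0.113 with an estimated correlation.

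On day 6 at 25% the largest rises by the rule were in A1BG-AS1, MMP9 and the splicing kinase gene CLK1, which rose from 132 ± 52.5 to 682 ± 46 normalized counts (log2 change 2.43 ± 0.23 SE, adjusted p = 2.82e-07), n = 3 and 2. MMP9 was at 60.2 ± 5.64 against 8.15 ± 4.12 normalized counts. The largest falls were in PDCD6P1, CCDC66 and CDR2L. CDR2L went from 58 ± 10.2 to 10.8 ± 0.644 normalized counts (log2 change -2.31 ± 0.44 SE, adjusted p = 0.00088), while the call of the antisense RNA A1BG-AS1 (adjusted p = 0.0376) ended without either 25% library or 100% replicate 1, that of CCDC66 (0.033) without 25% replicate 2 or any one 100% library, and that of PDCD6P1, a pseudogene, without 25% replicate 3. Antisense RNAs are uncertain here, since the strand setting of the counting is not given in the sources used here. Of the 2577 genes 1277 rose and 1300 fell. The count was 1398 without 25% replicate 2 and 1261 without replicate 3, where a lone library is assumed to vary like the other groups, and 914 without the keratin-high libraries, which include 2 of the 3 controls. Without them HMGCS1 and SLC7A11 also lost their calls (adjusted p = 0.0602 and 0.109). Their log2 changes were -0.70 ± 0.12 SE and 0.63 ± 0.13 SE with all libraries and -0.56 ± 0.16 SE and 0.59 ± 0.20 SE against the 1 remaining control. The folds stayed close, so the lost calls do not show keratin as a cause.

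On day 9 at 25%, 1768 genes rose and 1647 fell. Among the largest rises were those of LAMB3 and CDRT4, and the largest falls were in TRO, PRMT7 and ABCA5. The call of CDRT4 ended with the keratin covariate (log2 change 2.27, adjusted p = 0.146, from 3.13) and in a fit on the compared groups. With the 1 library at 25% that was not keratin-high its log2 change was 3.20. The call of PRMT7 ended in a fit on the compared groups (adjusted p = 0.0506). TRO fell from 63.5 ± 21.3 to 2.56 ± 4.44 normalized counts (log2 change -4.91 ± 0.69 SE, adjusted p = 1.82e-05), n = 3 in each group, and ABCA5 had a log2 change of -2.04 (adjusted p = 0.00156). LAMB3, which epithelial cells express, was at 67.5 ± 98.1 against 1.27 ± 1.38 normalized counts (log2 change 3.86, adjusted p = 0.00826), and its call ended without 25% replicate 3. In that library KRT8, KRT18 and KRT19 added up to 1358. Without the libraries where this sum was over 100 the comparison called 1216 genes, in a fit with 1 of the 3 libraries at 25%. Of 29 replication-dependent histones 5 rose (5 adjusted over the list alone, adjusted p = 0.671 with an estimated correlation), and the 13 other RNAs without poly(A) tails had a median log2 change of 0.70.

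**Figure D3:**
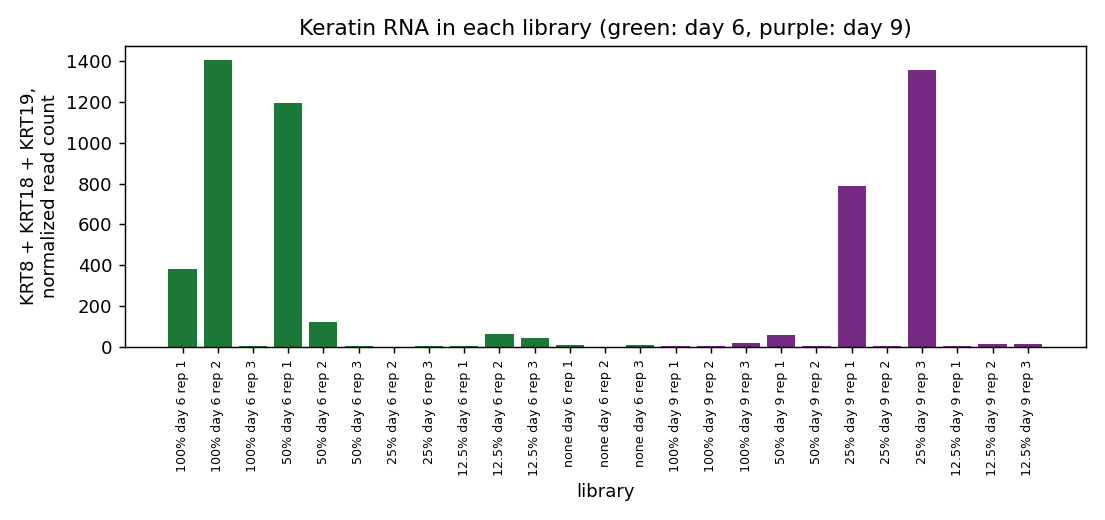
Sum of the normalized counts of KRT8, KRT18 and KRT19 (y axis) in each of the 25 libraries (x axis), with day 6 in green and day 9 in purple. The sum is over 100 in 2 of 3 libraries at 100% and 2 of 3 at 50% on day 6 and in 2 of 3 at 25% on day 9, and at most 60.3 in the other libraries.

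Adding the doses from 100% to 12.5% in 1 trend gave 5424 genes with a slope per halving of histidine on day 6 (2441 up, 2983 down) and 5130 on day 9 (2428 up, 2702 down). After upper-quartile rescaling 3024 slopes were up and 2566 down on day 6 and 2907 up and 2413 down on day 9. MMP9 rose by 1.05 and 1.10 per halving on the log2 scale (adjusted p = 8.11e-06 and 4.65e-06). On day 6 its mean at 12.5% was not above that at 25%, so the rise was not even over the doses. HMGCS1 fell by 0.46 and 0.54 per halving on days 6 and 9. Cholesterol synthesis genes fell in 20 and 21 of 23 cases (20 and 21 adjusted over the list alone, adjusted p = 0.044 and 0.0219 with an estimated correlation). Fatty acid synthesis genes fell in 10 of 12 cases on each day (10 and 10 adjusted over the list alone, adjusted p = 0.0561 and 0.027 with an estimated correlation). CCND2 had a slope of 1.31 on day 6 (adjusted p = 0.00655), which was lost without replicate 3 at 100%. It was at 0 to 13.9 normalized counts at 100%, at 0 in each library at 50% and 25%, and at 67.7 to 161 at 12.5%. The slope of CCND2 therefore came from the step to 12.5% and was not a graded rise. The slopes of 7SK and SCARNA2 on day 6 and of the pseudogene HLA-V on day 9 ended with the 5.8S rRNA level as a covariate. Leaving out 100% replicate 3, 25% replicate 3 or 12.5% replicate 1 or 2 ended the slopes of 7SK and SCARNA2, 100% replicate 1 also that of 7SK, and any one 100% library, 50% replicate 2 or 12.5% replicate 1 or 2 that of HLA-V. A straight line does not describe the mitotic genes, which were higher at 25% than at 100% or 12.5%. In comparisons chosen after the data were examined, 28 of 30 were lower at 12.5% than at 25% on day 6 (28 adjusted over the list alone) and 29 on day 9 (30 adjusted over the list alone), with adjusted p = 0.0207 and 0.000411 with an estimated correlation. Across the slopes of the days, 11 and 9 lists passed with the preset correlation and 1 and 2 with an estimated one. The day 6 slope count was 2636 without the keratin-high libraries.

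Genes of the amino acid response, which ATF4 controls, did not move in one direction. Of 31 tested, 7 rose and 9 fell at 12.5% on day 6 (8 and 12 adjusted over the list alone) and 6 rose and 7 fell without histidine (7 and 9), where the list's median was -0.07 and its mean 0.02. On day 9, 7 rose and 4 fell at 12.5% (8 and 4), and the list passed in none of these comparisons (adjusted p = 0.263, 0.984 and 0.2). The pseudokinase gene TRIB3 (chromosome 20, 362835 to 397559) went from 10342 ± 291 to 4373 ± 379.5 normalized counts (log2 change -1.25 ± 0.11 SE, adjusted p = 2.46e-08) on day 6 at 12.5% and fell less without histidine (log2 change -0.70, adjusted p = 2.22e-05). DDIT3, which encodes CHOP, fell at 12.5% on day 6 (log2 change -0.77, adjusted p = 2.33e-05) and had a log2 change of 0.05 without histidine (adjusted p = 0.773). The cystine transporter gene SLC7A11 rose by 0.89, 0.97 and 0.56 at 12.5% on day 6, without histidine and at 12.5% on day 9. Asparagine synthetase ASNS was low, at 23.2 ± 19.2 normalized counts in full medium and 71.1 ± 17.8 at 12.5% on day 6, and did not pass (log2 change 1.84, adjusted p = 0.051). The glutathione-degrading enzyme gene CHAC1 rose at 25% (log2 change 0.66, adjusted p = 0.0222 on day 6), a call lost without either 25% library or 100% replicate 1 or 2, and not at 12.5% (log2 change 0.08, adjusted p = 0.765). Histidyl-tRNA synthetase HARS1 was lower at 12.5% on day 6 (log2 change -0.28, adjusted p = 0.0232) and day 9 (log2 change -0.29, adjusted p = 0.0228). The first call ended without 100% replicate 1 or 2 or 12.5% replicate 1 or 2 and the second without 100% replicate 2 or 3 or 12.5% replicate 3. Both ended in a fit on the compared groups. The first also ended with upper-quartile rescaling (-0.19, adjusted p = 0.0673) and quantile normalization (-0.19, adjusted p = 0.0647). Against the 1 control without high keratin the day 6 log2 change of HARS1 was -0.14. Without histidine it was -0.10 (adjusted p = 0.462). MYC was lower at 25% on day 6 (log2 change -0.53, adjusted p = 0.000201) and had a log2 change of -0.24 at 12.5% on day 6. The latter call ended without 100% replicate 1 or 3 or any one 12.5% library. It also ended with upper-quartile rescaling (-0.15, adjusted p = 0.0995), quantile normalization (-0.10, adjusted p = 0.365), the 5.8S rRNA covariate or a fit on the compared groups. Without histidine the log2 change of MYC was -0.02 (adjusted p = 0.871). HES1 and CDKN1A fell at 12.5% on day 6 (-0.43 and -0.98). MKI67 rose there by 0.41, a call that ended without 100% replicate 1 or 3 or 12.5% replicate 1 or 2. That call also ended with no mean trend, the keratin covariate or the 5.8S rRNA covariate. At 25% on day 9 MKI67 rose by 0.52, a call that ended with quantile normalization (0.54, adjusted p = 0.0749). With the 1 library at 25% that was not keratin-high its log2 change was 0.55.

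**Figure D4:**
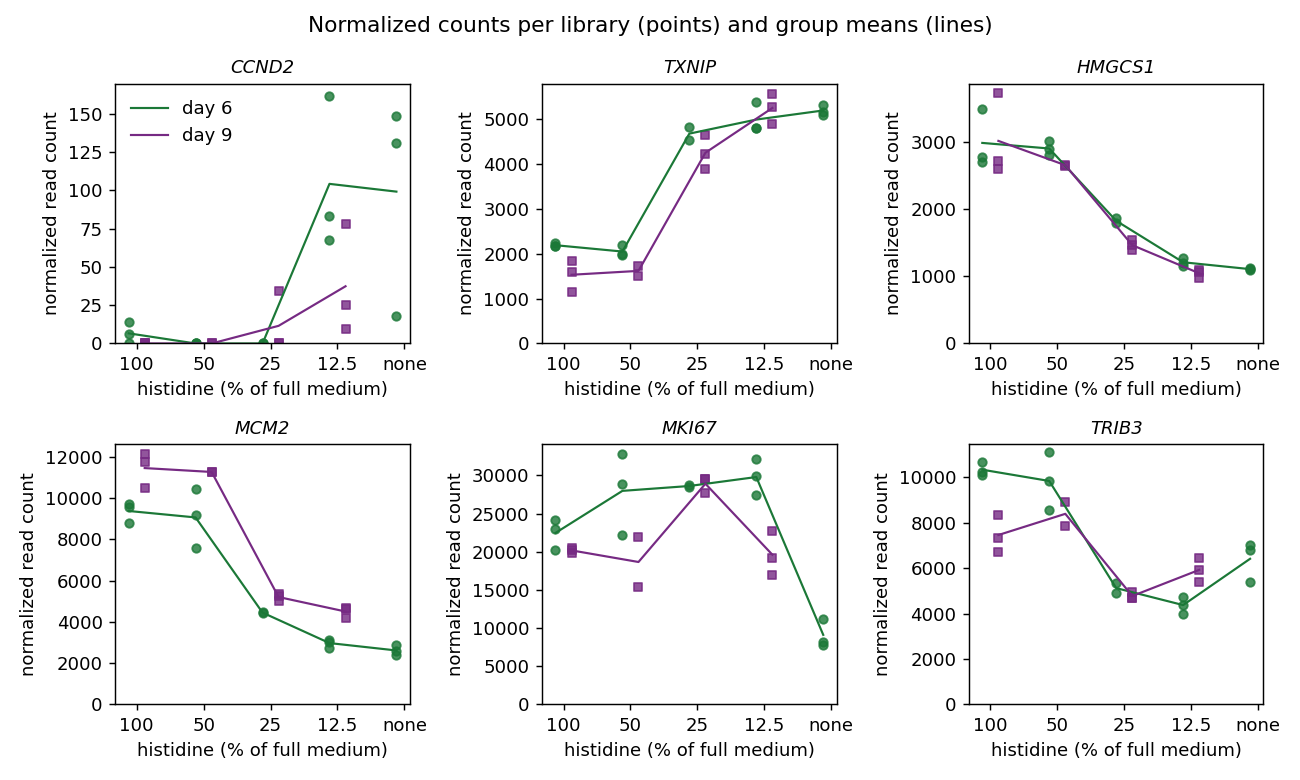
Normalized read counts of 6 genes in each library (points) and group means (lines) on the y axis, against histidine in the medium (x axis, % of full medium) on day 6 (green) and day 9 (purple). TXNIP, chosen after its values were seen, has log2 changes of 1.19 and 1.80 at 12.5% on days 6 and 9, while HMGCS1 and MCM2 are lower at each level from 25% down and MKI67 is lower without histidine.

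Between day 9 and day 6 in full medium 206 genes rose and 202 fell, and 31.8% of calls were rises after upper-quartile rescaling against 50.5% as deposited. The immediate-early transcription factor gene EGR1 fell from 5830.2 ± 641 to 1164 ± 507 normalized counts (log2 change -2.41 ± 0.20 SE, adjusted p = 2.87e-07), n = 3 in each group, and FOS and the phosphatase gene DUSP2 had log2 changes of -2.52 and -1.76. The largest rises were in CLK1 (log2 change 1.83, adjusted p = 2.42e-05), ABCA5 and the splicing factor gene RBM39 (log2 change 1.33, adjusted p = 7.99e-05), and the call of ABCA5 (adjusted p = 0.0419) ended when any one of the 100% libraries except day 6 replicate 1 was left out. Of 13 mitochondrially encoded genes 5 fell (13 adjusted over the list alone, median log2 change -0.74, adjusted p = 0.335 with an estimated correlation). In all 13 lists passed with the preset correlation and none with an estimated one. The day count of 408 was lower without any one of its 6 libraries, between 151 and 332. Fewer libraries alone also lower a count, but each of these fits left out 1 library, so the count also varied with which one. It was lowest without day 6 replicate 2, which had a keratin sum of 1406, and highest without day 9 replicate 1. The cause of this range was not tested. Of the 3 day 6 libraries 2 had keratin sums over 100, and without them 21 genes were called.

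Whether the response to histidine differed between the days was tested as an interaction. At 12.5% there were 12 such genes, of which 8 were relatively higher and 4 relatively lower on day 9, and 1887 had an unadjusted p under 0.05. ACY1 had log2 changes of -3.28 on day 6 and -0.41 on day 9 (difference 2.87 ± 0.53 SE, adjusted p = 0.0332). WNK4 had log2 changes of 2.43 on day 6 and 0.53 on day 9. Those of SLC6A20 were 1.63 and 0.39. At 25%, SRSF5 alone passed (log2 changes 0.10 and -0.98, adjusted p = 0.011), with 1034 at an unadjusted p under 0.05, and at 50% no gene passed in the limma test, with 802. Leaving out 1 library moved the 12.5% count to between 2 and 19 and the 25% count to between 0 and 5, and without the keratin-high libraries 1 of the 12 genes was still called at 12.5%, with 2 others, and none at 25%. The call of SRSF5 ended without 100% replicate 3 of either day, 25% replicate 2 of day 6 or 25% replicate 3 of day 9. That of ACY1 ended without any one library except 12.5% replicate 3 of day 6 and 100% replicate 3 of day 9. That of WNK4 ended without any one except 100% and 12.5% replicate 3 of day 6, and that of SLC6A20 without any one except 100% replicate 2 and 12.5% replicate 3 of day 6. Each of these 4 calls also ended with no mean trend, the keratin covariate or a fit on the compared groups, or without the keratin-high libraries, and those of ACY1 and WNK4 with the replicate block.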

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

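The tests of keratin against histidine level and against scaling, of histones against other RNAs without poly(A) tails and against S phase, and the fits with keratin and 5.8S rRNA were chosen after the result was seen.

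The response to 12.5% histidine differed between the days for 12 genes by the interaction test. Among them the difference (day 9 minus day 6, log2) was 4.74 for CNTN3, 0.72 for STK32B, 0.91 for TRIB3, 0.70 for CEBPB, 0.86 for SLC2A4RG, 2.87 for ACY1 and 0.90 for RMI2. It was -1.08 for RGS1, -1.23 for SLC6A20, -1.90 for WNK4 and -0.74 for RASSF2. At 25% it was -1.09 for SRSF5. Of 100 splits of the samples 8 gave as many genes as the 12 at 12.5%, the real one included, so chance was not excluded there, and the highest other split called 309. A split that calls that many points to a structure of the samples, and since days were exchanged within each dose it can carry a day difference common to both doses, but which structure it was has not been tested.

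Lists also differed between the days with the preset correlation and not with an estimated one. At 50% the median differences were 1.14 for replication-dependent histones, 0.29 for ribosomal proteins, 0.25 for nuclear genes of oxidative phosphorylation and 0.27 for mitochondrially encoded genes, with adjusted p = 0.832 for each with an estimated correlation. At 25% they were -0.15 for cholesterol synthesis (adjusted p = 0.795 with an estimated correlation), -0.27 for G1/S and DNA replication and 0.23 for G2/M and mitosis (0.288 each) and 6.94 for epithelial and fibroblast markers (0.6). At 12.5% they were 0.19 for the amino acid response, 0.17 for G1/S and DNA replication, 0.88 for histones, 0.39 for ribosomal proteins, 0.79 for mitochondrially encoded genes and 0.16 for the unfolded protein response, with adjusted p = 0.699 for each, and 0.20 for oxidative phosphorylation (0.827).

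KRT8, KRT18 and KRT19 were high in 6 libraries of 3 groups, with sums of 383 and 1406 at 100% on day 6, 1196 and 119 at 50% on day 6 and 788 and 1358 at 25% on day 9, and the within-group log2 range reached 8.31, which argues against histidine level as the whole cause. The share of variance between groups, 46.4% with a permutation p of 0.165, was the first test of that and was replaced after it was seen. After quantile normalization the log2 range of KRT8 over 25 libraries was 9.87, which argues against scaling. A second list of epithelial genes, which could mark RNA of epithelial cells, had a Spearman rho of 0.542 with the keratin level over 25 libraries (permutation p = 0.0054, adjusted 0.0241 over 6 relations, Pearson r = 0.702), 0.086 in the 19 libraries up to 100 and 0.943 in the 6 over 100 (exact permutation p = 0.0167). Within day 6 and day 9 rho was 0.521 and 0.445 (permutation p = 0.0582 and 0.171). There r was 0.679 and 0.773 (permutation p = 0.00408 and 0.00752, adjusted 0.0113 each), with r of 0.317 and -0.0774 without the 2 farthest libraries. Of the list's genes KRT7 reached 64.5 in the 6 libraries against 2.74 elsewhere and SPINT1 35.3 against 1.03. TRPS1 reached 662 against 666 and GREB1 275 against 248, levels at which a small addition could be hidden. The rho over 25 libraries met a prediction set beforehand. The 2 farthest libraries had the highest keratin sums of their day, 1406 and 1196 on day 6, 788 and 1358 on day 9. RNA of epithelial cells confined to such libraries would also leave a weaker relation without them. The lower r without them therefore cannot decide on this explanation. RNA of epithelial cells remains a hypothesis. Apart from histidine level no other biological explanation was tested.

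Replication-dependent histones had a median log2 change of -1.22 at 12.5% and -0.39 without histidine on day 6, and -1.54 at 12.5% after quantile normalization, which argues against scaling. At 50% and 25% on day 6 the histone median was -1.01 and 0.64 (-0.88 and 0.13 for other RNAs without poly(A) tails). Replication-dependent histones thus did not follow the histidine level in order. In none against 12.5% their median was 0.70 while that of G1/S genes was -0.55, which argues against fewer cells in S phase as the whole cause and leaves them open as a part, since other RNAs without poly(A) tails rose by 0.91 there too, in a test that replaced a first one on opposite signs across comparisons after that one was seen. Within-group deviations of the histone mean went with those of 13 other RNAs without poly(A) tails (Pearson r = 0.822, permutation p = 0.00574, adjusted 0.0113 over 6 relations, Spearman rho = 0.711, permutation p = 0.00805, r = 0.693 without the 2 farthest libraries). With 5.8S rRNA as a covariate the median was 0.10 at 12.5%, 0.40 without histidine and 0.27 in none against 12.5%. The share of RNA without poly(A) tails kept in each library is a candidate explanation, found and tested on the same data.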

How the results depend on the processing

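The keratin and 5.8S rRNA fits and the fit without keratin-high libraries were chosen after the data were examined. No named gene past the threshold turned direction. The median of the mitochondrially encoded list at 12.5% on day 6 turned from -0.29 to 0.05 under quantile normalization. It also turned in comparisons where the list did not pass: from -0.22 to 0.02 without histidine, 0.20 to -0.01 in none against 12.5%, 0.07 to -0.01 at 50% on day 9, -0.08 to 0.03 for the day 6 slope and 0.09 to -0.10 for the 25% interaction. With 5.8S rRNA the histone median turned from -1.22 to 0.10 at 12.5% and -0.39 to 0.40 without histidine on day 6, -0.34 to 0.24 at 12.5% on day 9, -0.22 to 0.10 for the day 6 slope, -0.28 to 0.11 for day and 0.28 to -0.03 for the 25% interaction. With upper-quartile rescaling more genes were higher than lower at 12.5% on day 6 (2851 and 2384) and day 9 (2163 and 1940), without histidine (3158 and 2786) and for the slopes of day 6 (3024 and 2566) and day 9 (2907 and 2413), where fewer were as deposited. Over named genes, leaving out each library kept 2345 calls on their side of the threshold, weakened 177 and strengthened 6. Of 367 such values the other settings weakened 47 without keratin-high libraries, 31 on compared groups, 23 without a mean trend, 17 with the keratin covariate, 15 with 5.8S rRNA, 7 with quantile normalization, 7 with the replicate block, 5 with upper-quartile rescaling, 3 without a filter, 3 and 1 with pseudocounts of 8 and 0.5, 2 with library weights and 1 without the library of conflicting days. Counts within 1.5 times the reported one are not repeated, and the cause was not tested for those that follow. Depth is not known, so what it limits was not assessed. The planned count tests on recovered reads were not run, since reads were not recovered.

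Without a filter 50% on day 9 had 2 genes and day 266. The 25% interaction had 2 with upper-quartile rescaling, 3 with quantile normalization, 0 without a mean trend, 8 with library weights, 0 with the keratin covariate, 0 without keratin-high libraries, 2 with 5.8S rRNA and 0 on compared groups. The 12.5% interaction had 3 without a mean trend, 133 with library weights, 2 with the keratin covariate, 3 without keratin-high libraries, 41 with 5.8S rRNA and 1 on compared groups. At 50% on day 9 no gene passed with limma (0, against 906 at an unadjusted p under 0.05 as reported) with quantile normalization, library weights, the keratin covariate, without keratin-high libraries or on compared groups. Library weights gave 292 at 50% on day 6, 4967 for none against 12.5% and 1069 for day. Without keratin-high libraries there were 1 at 50%, 914 at 25%, 2464 at 12.5% and 3239 without histidine on day 6, 1216 at 25% on day 9, 2636 for the day 6 slope, 21 for day and 1 for the 50% interaction, from fewer samples. Compared groups alone gave 1 at 50% on day 6, 1184 for none against 12.5% and 135 for day. With an estimated correlation 13 list calls held of 129.

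Leaving out 1 library gave 1261 to 2069 genes at 25% on day 6, 151 to 332 for day, 0 to 1 for the 50% interaction, 0 to 5 at 25%, 2 to 19 at 12.5%, 1750 to 3309 for none against 12.5% and 0 to 11 at 50% on day 9.

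With the replicate number as a replicate block, 50% on day 9 had 0 genes and 127 list calls were made. None of 92 same-number pairs had a correlation over 0.1 (-0.128 to 0.0819), and 9 of 25 libraries correlated best with their own number.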

Other observations

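The test of histidine codons was chosen after the result was seen, and the others here before.

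The no-histidine library labelled with 2 days lay on the far side of the other no-histidine libraries from day 9, over 2440 genes that differed between days. Its mean log2 score lay at -0.172 from theirs, or -0.484 of the day gap of 0.355 in the 50% and 25% groups, while those libraries differed from each other by 0.0293 on the same log2 scale. The library thus showed no shift towards day 9. It stood apart from the others all the same, and the day gap had to be taken from other doses. The test therefore did not settle its day. Without this library none against 12.5% called 3309 genes.

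A hypothesis that messages rich in histidine codons fall when histidine is restricted came with a prediction only for 12.5% and no histidine on day 6, where it was not borne out. Across 12667 genes, which are not independent replicates, Spearman's rho between the share of histidine codons and log2 change was 0.00996 and 0.00174 there. In the other comparisons with 100% histidine it was 0.0411 at 50% and -0.0994 at 25% on day 6, -0.0436 at 50%, -0.0967 at 25% and -0.0375 at 12.5% on day 9, and -0.0199 and -0.0526 for the slopes. A weak relation there was not separated from the GC content and length of the coding sequence, whose rho reached -0.177 for GC content at 25% on day 6 and 0.227 and -0.219 for length at 50% on day 6 and day 9.

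For groups of 3 against 3 there are 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 0 and 1 at 50% on day 6, 5072 and 0 at 12.5%, 5611 and 0 without histidine, 2869 and 789 for none against 12.5%, 3415 and 0 at 25% on day 9, 3916 and 1 at 12.5% on day 9 and 408 and 1 for day. As many genes as the real split came from 10 of 10 splits at 50% on day 6 and from 1 of 10 in the others. For the slopes 1 of 100 splits, the real one, gave as many genes as the 5424 and 5130 observed. The highest others called 3293 and 3159. That share is under 0.05 and is the smallest that 100 splits can give. Exchanging libraries does not test chance between cultures, since the replicates may be technical.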
